A study of Mus musculus with 8 samples.

How the data were processed

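Liver RNA from male C57BL/6J mice was measured on 8 arrays, 4 from mice on standard chow (control) and 4 from mice on a high-fat diet, after 16 weeks of feeding. Per the labels' protocols, RNA was amplified and labelled with Cy3 by a random-priming method that covers the length of the transcript, and hybridised to a 1-colour Agilent array for long non-coding RNA and mRNA. The labels count 32 mice in the study and give each array a number of its own, with no number shared between the diets. They do not say in so many words that each array is 1 mouse, so p-values measure the spread between these samples.

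The scanner files hold spot intensity on a linear scale, made with Agilent Feature Extraction 11.0.1.1 per the file headers. The processed signal in them is background-corrected by that software. The deposited value table holds log2 values whose array medians all lie near 4.84, and each column correlates with the log2 scanner signal of its own array between 0.986 and 0.995. Its even medians show that the arrays were scaled to one another, but the method is not given in the sources used here. It covers 60641 probes, those printed once, so it holds none of the probes that carry an accession. Array grids name the mm9 build per the file headers, and no coordinates are printed.

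Each array has 62976 features. After control features were left out, 61537 spots of 60823 probes remained: 60641 probes printed once, 132 printed 3 times and 50 printed 10 times. Spots marked as outliers were left out, between 0.0650% and 0.112% per array, and no spot was saturated. The log2 processed signal minus the array's 75th percentile was averaged over the spots of a probe. A probe was tested when it was well above background on all 4 arrays of at least 1 diet, with at least 50% of its spots above background on an array. This left 39426 probes, 64.8% of all. The diets were compared with lmFit and eBayes in limma 3.58.1 (R 4.3.3), 2-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The prior degrees of freedom came to 3.90. Figures were drawn with matplotlib 3.10.9. The number of arrays limits the precision.

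Only 50 probes carry an accession, and 46 of them matched a symbol in the RefSeq gene table of assembly GRCm38.p6. Of the 43 tested, 41 have a symbol. The other probes have the maker's identifier alone and were not named. Identifiers that contain LNC or lincRNA were counted as long non-coding. No file marks a probe as mRNA, so the planned count of mRNA probes was not run, and the AP1B family of identifiers is given by its name only. The planned tests of 28 gene lists need at least 5 tested members, which 0 lists had. Genes were named by a rule: the 10 per direction with the largest change past the threshold and no overlap between the diets, filled in order of p; the same for long non-coding identifiers, of which at most a pair per direction is printed; and members of the gene lists. A result that the rule named is not reported here. The rule also held a set of liver lipid, inflammation and fibrosis genes that no named probe covers, and these were not analysed here. Where a probe was not well above background on any array of a diet, the fold is a lower bound. It sets the brighter diet's mean against the dim diet's mean of, per array, the higher of the lowest signal well above background and the probe's own signal.

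All 8 arrays share 1 slide and 1 scan date. Slide row 1 holds the control arrays and slide row 2 the high-fat arrays, so slide row and diet cannot be told apart. The slide could not be used as a block. The limma step was tested on simulated data: 10 simulations of 39314 probes with independent noise, each with 200 changed probes. It recovered 62.5% of changes of 2-fold and 95.2% of changes of 4-fold, with 7.50 false calls on average. The called probes of the real data varied together, with a mean pairwise residual correlation of 0.633, which independent noise leaves out. The false-call figure therefore does not carry over to those calls.

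Fixed before the data were examined were the tests, the naming rule and these alternatives: quantile normalization, median centring, no filter, a filter on all 8 arrays, the deposited values, eBayes with trend and robust settings, array weights, other thresholds and leaving out each array. Chosen after seeing the data were normexp (offset 50) on median signals, slide column as a block, keeping outlier spots, and adjustment over the accession-named probes alone. The planned normexp on mean signals was not run, since the scanner files used here hold median signals. The 3 control-probe measures of PGK1 were added to the array-quality family after their values had been seen, and mean background took the place of median background, which was 12 on every array.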

Results

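Liver RNA was profiled on 8 arrays, 4 from control mice and 4 from mice on a high-fat diet for 16 weeks, a feeding model of non-alcoholic fatty liver disease. The comparison asks which long non-coding RNAs and mRNAs differ in the liver between the diets. The 75th percentile of signal was 138 ± 4.72 (SD, n = 4) in control arrays and 145 ± 15.5 (SD, n = 4) in high-fat arrays (exact permutation test, 2-sided, p = 0.429). On average 69.5% ± 2.95 of probes were well above background in control arrays and 68.2% ± 4.32 in high-fat arrays (SD, n = 4 each; exact permutation p = 0.6). All values below are log2 signals relative to the array's 75th percentile, and changes are high-fat minus control.

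Among genes that could be named, Olfr166, an olfactory receptor gene, was the 1 that passed the threshold. Its signal was 1.82 ± 0.53 in control livers and 3.72 ± 0.39 in high-fat livers (SD, n = 4 each), a 3.73-fold rise. The log2 change was 1.90 with SE 0.27 and a 95% interval from 1.29 to 2.51 (limma adjusted p = 0.0428). All 4 high-fat arrays lay above all 4 control arrays, and all 10 spots of the probe were higher on average under the high-fat diet. Olfactory receptors form a family with closely related copies, so which member the probe reads is uncertain. Whether its signal comes from an olfactory receptor transcript at all was not tested. In high-fat livers it lay above the signal of Actb, at 1.98 ± 0.34 (SD, n = 4). That sets signals of different probes side by side, not amounts of RNA. Within each diet Olfr166 ordered the arrays as the mean of all probes called higher did. The Olfr166 call is fragile: leaving out 1 array ended it in 6 of 8 fits, with adjusted p from 0.106 to 0.163 in those, although the change stayed between 1.74 and 2.15 over all 8. It also ended with no filter (adjusted p = 0.138), with normexp (0.0742) and with slide column as a block (0.232), and held when adjustment covered the accession-named probes alone (0.00185), a choice made after seeing the data.

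**Figure D1:**
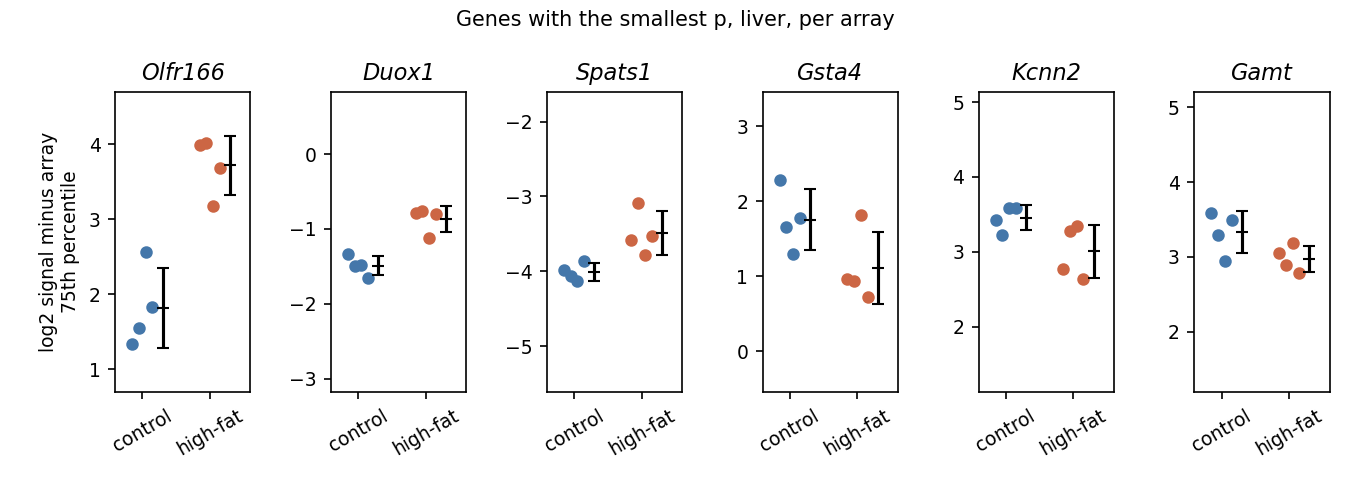
Per-array log2 signal minus the array's 75th percentile (y axis, 4 units high in each panel) for 6 named genes in control and high-fat livers; points are arrays and the bar beside them is the mean ± SD, n = 4. Olfr166 lies between 1.34 and 2.56 in control arrays and between 3.17 and 4.02 in high-fat arrays, and the other 5 genes did not pass the threshold.

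Duox1, a dual oxidase that makes hydrogen peroxide, came next and did not pass the threshold. Its signal was -1.49 ± 0.13 in control livers and -0.87 ± 0.17 in high-fat livers (SD, n = 4 each), with no overlap between the diets. The log2 change was 0.62 with a 95% interval from 0.34 to 0.90 (limma adjusted p = 0.0675). Duox1 passed with array weights (adjusted p = 0.0466), without high-fat replicate 31 (0.0248), and when adjustment covered the accession-named probes alone (0.0140), a choice made after seeing the data. Across all alternatives its adjusted p ran from 0.0140 to 0.277, and with normexp its change was 0.32. Spats1, a spermatogenesis-associated gene, had a log2 change of 0.52 (adjusted p = 0.270) and was well above background on 1 control array and 4 high-fat arrays. With normexp the change of Spats1 was 0.051. The LIM homeobox gene Lhx1 had a change of 0.23 (adjusted p = 0.726). On the same side, Olfr1307, Rab5a, Hyal3, Anxa8 and Cep41, had changes of 0.10 or less and adjusted p of 0.884 or more.

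No named gene passed the threshold on the lower side. Gsta4, a glutathione S-transferase that conjugates products of lipid peroxidation, had a log2 change of -0.64 with a 95% interval from -1.23 to -0.05 (limma adjusted p = 0.517), and 3 of 4 high-fat arrays lay below all control arrays. Kcnn2, a calcium-activated potassium channel gene, had a change of -0.45 with an interval from -0.85 to -0.05 (adjusted p = 0.501). Gamt, which catalyses the last step of creatine synthesis, had a change of -0.35 (adjusted p = 0.583). Bambi, a decoy receptor of the TGF-beta family, had -0.33 (adjusted p = 0.671) and Lhfp had -0.42 (adjusted p = 0.721). The small heat shock gene Hspb7 had -0.56 (adjusted p = 0.737) and was well above background on 4 control arrays and 2 high-fat arrays. Taf1a, Rps4l, Gm9789 and Il2 had changes between -0.23 and -0.13, with adjusted p of 0.727 or more. Rps4l belongs to a ribosomal protein family with near-identical copies, so its value is uncertain.

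The fatty acid oxidation and PPAR alpha list had 4 named members, all bright and none past the threshold. Ppara, the receptor that drives fatty acid oxidation genes in liver, was 4.98 ± 0.14 in control livers and 4.99 ± 0.23 in high-fat livers (SD, n = 4 each), a log2 change of 0.01 with a 95% interval from -0.30 to 0.33. Cpt1a, the enzyme that admits long-chain fatty acids to mitochondria, had a change of -0.07 with an interval from -0.35 to 0.21. Acaa2, a mitochondrial thiolase, had -0.03 (from -0.31 to 0.25), and Pex11a, a peroxisome proliferation gene, had -0.06 (from -0.43 to 0.30). The mean of the 4 genes was 6.39 ± 0.07 in control livers and 6.35 ± 0.09 in high-fat livers (SD, n = 4 each; exact permutation test chosen afterwards, p = 0.571), and 0 of the 4 passed when adjusted over the list alone. Gsta4 was the 1 named member of the NRF2 and oxidative stress list, so neither list had the 5 tested members that the planned set test needs. The lipoprotein gene Apoe, chosen after its values were seen, had a change of 0.03 (from -0.26 to 0.32). Signs this close to 0 turn with the scaling: Ppara was -0.08 after quantile normalization and Acaa2 was 0.01 after median centring.

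**Figure D2:**
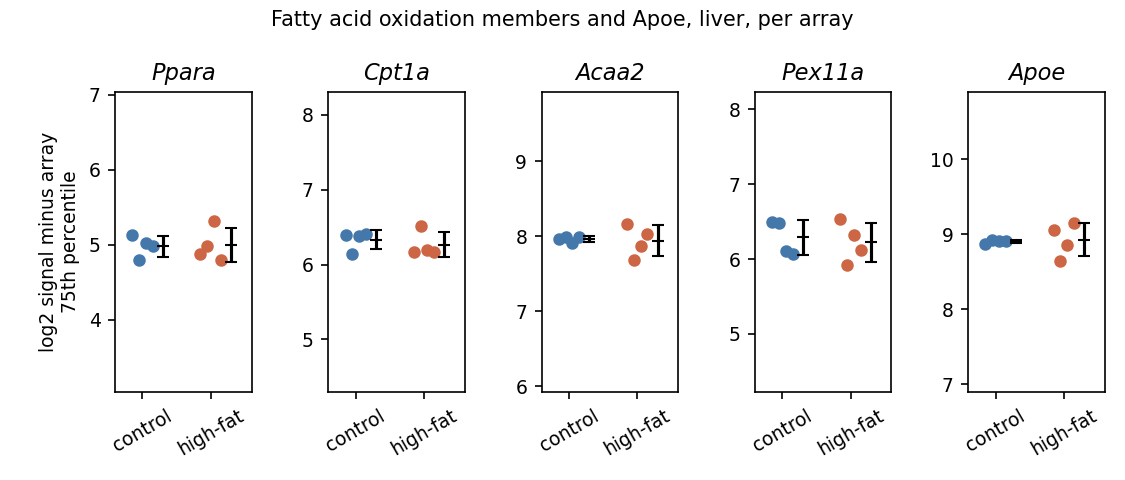
Per-array log2 signal minus the array's 75th percentile (y axis, 4 units high in each panel) for 4 fatty acid oxidation members and Apoe in control and high-fat livers; points are arrays and the bar is the mean ± SD, n = 4. The groups overlap for each gene, as for Ppara with means of 4.98 and 4.99.

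Across all 39426 tested probes, 249 were higher and 13 lower under the high-fat diet at adjusted p under 0.05 with limma, 262 in all. Of these, 226 had a fitted change of at least 2-fold, and 215 did with probes not well above background in a diet set at their bound. With such probes at their bound, the median log2 change was 1.45 among the higher calls and -0.61 among the lower calls, 7 of which were not well above background on any high-fat array. Signals of the 4 high-fat arrays did not overlap those of the 4 control arrays for 2180 probes, 5.53% of those tested. Chance gives 2.86% on average over splits of the arrays. How widely this share varies between splits was not computed, so an excess over chance is not shown. By family of identifier, the AP1B family had 89 higher and 3 lower calls among 16279 tested probes, and the P family 31 higher and 1 lower among 4195. The adjusted p of the calls lay between 0.0428 and 0.0496, just under the threshold, and 0 probes were called in 6 of the 8 fits that left out 1 array, with no filter, with normexp, or with slide column as a block. The called probes also varied together within each diet, with a mean pairwise correlation of 0.633, so they are not 262 separate observations. The log2 ratio of the PGK1 control probes, given below, also did not overlap between the diets.

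**Figure D3:**
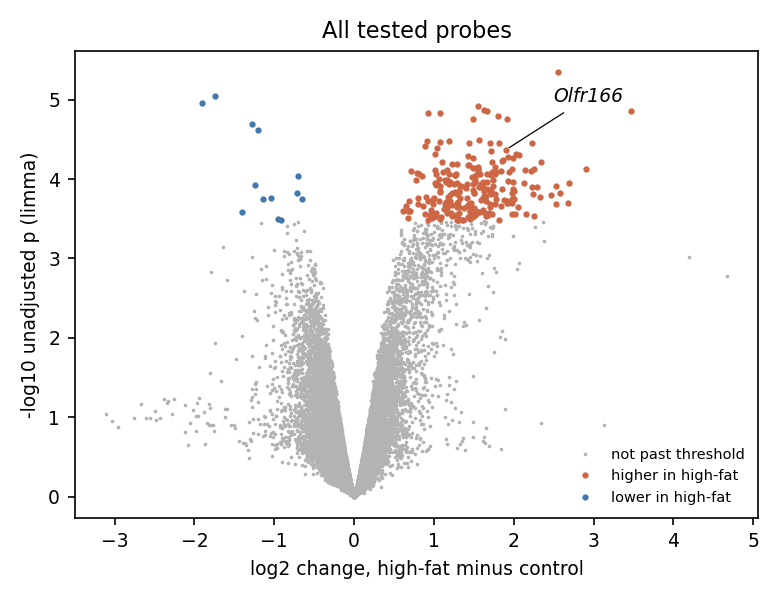
Log2 change, high-fat minus control (x axis), against -log10 of the unadjusted limma p (y axis) for the 39426 tested probes, n = 4 arrays per diet. Coloured points passed the threshold, 249 higher and 13 lower, and Olfr166 is marked.

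Among long non-coding identifiers, 125 were higher and 9 lower under the high-fat diet, of 18601 tested. LNC1A identifiers held 112 of the higher and 8 of the lower calls, humanlincRNA identifiers 10 and 1, and mouselincRNA identifiers 2 and 0. These families had 18060, 321 and 191 tested probes, of which 0.664%, 3.43% and 1.05% were called, against 0.665% of all tested probes. The largest rise was that of ASMM10LNC1A103619474V4, from -3.51 ± 0.72 in control livers to -0.04 ± 0.83 in high-fat livers (SD, n = 4 each), a log2 change of 3.47 with SE 0.44 (limma adjusted p = 0.0428), well above background on 3 control arrays and 4 high-fat arrays. ASMM10LNC1A105444313V4 rose from 1.25 ± 0.96 to 4.15 ± 0.59 (SD, n = 4 each), a change of 2.91 with SE 0.45 (adjusted p = 0.0428). On the lower side, ASMM10LNC1A100104707V4 had the largest fall among long non-coding identifiers measured on both sides, from -0.12 ± 0.40 to -1.35 ± 0.23 (SD, n = 4 each), a change of -1.24 with SE 0.20 (adjusted p = 0.0428). The signal of humanlincRNA1807+_P1V4 was not well above background on any high-fat array, and its bound there was at least 1.1-fold lower. The adjusted p of 0.0428 (limma) belongs to its fitted change of -1.74, not to this bound, which was not tested. The genes behind these identifiers are not given in the sources used here. All 4 lost their call in the same 6 fits that left out 1 array, with no filter, with normexp and with slide column as a block, and ASMM10LNC1A105444313V4 and ASMM10LNC1A100104707V4 also with quantile normalization (adjusted p = 0.0501 and 0.0503). With normexp the change was 1.505 for ASMM10LNC1A103619474V4 and -0.76 for ASMM10LNC1A100104707V4, and the fitted change of humanlincRNA1807+_P1V4 was -0.18 (adjusted p = 0.534), against -0.92 with the deposited values and -1.74 in the planned fit.

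Control arrays lay closer to one another than high-fat arrays did. Pearson correlations across tested probes averaged 0.989 between control arrays, 0.982 between high-fat arrays and 0.982 between the diets. The first principal component held 29.0% of the variance, with the 4 control arrays between -39.6 and -9.85 and the high-fat arrays between -3.07 and 65.4. Control-probe signals of PGK1, a glycolytic enzyme, did not overlap between the diets. The difference did not pass adjustment, but even full separation of 4 against 4 arrays could not pass beside the other measures of this family. The probe whose name ends in 3 was 7.08 ± 0.09 in control livers and 6.88 ± 0.10 in high-fat livers, and the probe whose name ends in 5 was -0.78 ± 0.10 and -1.15 ± 0.13 (SD, n = 4 each; exact permutation p = 0.0286 for each, the smallest that 4 against 4 allows, adjusted 0.0572 over 6 measures). The log2 ratio of the first probe to the second was 7.86 ± 0.10 and 8.03 ± 0.05 (exact permutation p = 0.0286, adjusted 0.0572). These probes were not checked under other scalings, and what the endings stand for is not given in the sources used here.

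**Figure D4:**
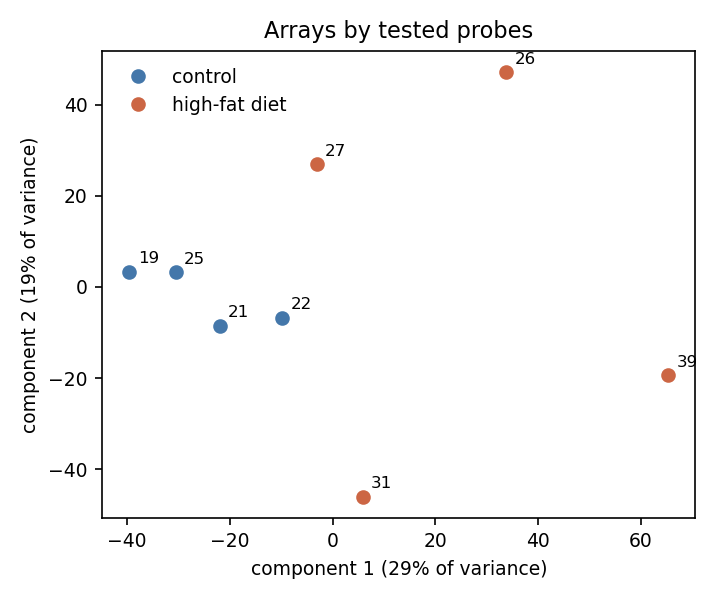
The 8 arrays on the first (x axis, 29.0% of variance) and second (y axis, 19%) principal component of the tested probes, numbered by replicate and coloured by diet. The 4 control arrays lie between -39.6 and -9.85 on the first component and the 4 high-fat arrays between -3.07 and 65.4.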

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

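The tests of dim probes as the source of the higher calls, and those of the spread among high-fat arrays, were chosen after the results were seen. In 78 sets of 4 arrays, 5 had 1 array far from the other 3, where chance gives about 3.9. Duox1 was -1.12 on high-fat replicate 31 and between -0.79 and -0.76 on the other high-fat arrays. Cpt1a was 6.14 on control replicate 21, against 6.38 to 6.41 on the other control arrays, and 6.51 on high-fat replicate 27, against 6.17 to 6.19 on the other high-fat arrays. The 75th percentile of signal was 131.4 on control replicate 19 and 139.9 to 141.6 on the other control arrays. The PGK1 probe whose name ends in 3 was 6.73 on high-fat replicate 39 and 6.92 to 6.94 on the other high-fat arrays.

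The 262 probes called between the diets, Olfr166 among them, were matched in number by 1 of the 35 splits of the 8 arrays, the real one, and the highest other split gave 0, though every call lay close to the threshold and leaving out 1 array gave 0 in 6 of 8 fits. At unadjusted p under 0.05 the real split had 3412 probes, the highest other 5164, and 4 of the 35 splits had as many. With a fold of at least 2 as well, the real split had 442, the highest other 374, and 1 of the 35 splits had as many. No measure can give a share under 1 of 35, and several were compared without adjustment, so chance is not excluded. The called probes were not crowded together on the array surface, where the median distance to the nearest called probe was 7.07 grid steps and the 5th percentile of 1000 random sets was 6.71. Within each diet they rose and fell together, with a mean pairwise residual correlation of 0.633 against a 95th percentile of 0.0102 in random sets. The calls may therefore stand for 1 shared difference. Slide column called 0 probes in limma, with 1026 at unadjusted p under 0.05, where chance gives about 1971 among the tested probes. Slide row and diet cannot be told apart, since each row holds 1 diet. Diet, slide row, a shared source such as 1 transcript read by many probes, and RNA quality, which was not tested directly, all stay open. The log2 ratio of the PGK1 control probes did not overlap between the diets, at 7.86 ± 0.10 in control and 8.03 ± 0.05 in high-fat arrays (SD, n = 4 each). Whether that ratio reads RNA quality is not given in the sources used here.

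Of the called probes, 95% were higher under the high-fat diet. The share of higher calls was at least 0.949 under median centring, quantile normalization and the deposited values. These were largely the same probes, 98 of 98 with quantile normalization and 126 of 129 with the deposited values, so the share could hardly move. The median log2 change over all tested probes lay between -0.023 and 0.021 under these scalings, against 1.45 among the higher calls. No shift common to all probes was thus left in the scaled values. Since these scalings level the arrays, a median near 0 was set in advance and cannot tell whether scaling gave the direction. Of the higher calls, 0.153 lay in the lowest 25% of probes by mean signal. That mean takes in the high-fat arrays, whose rise lifts a called probe, so it cannot settle whether dim signal matters. Among probes well above background on all 8 arrays, 280 calls were higher and 6 lower. The direction therefore did not rest on probes that were not well above background on some arrays. Diet remains a hypothesis for this direction, with slide row, scaling between arrays and dim signal still open.

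High-fat arrays differed more from one another than control arrays, with mean distances of 97.6 and 73.4 and a ratio of 1.33. As large a gap arose in 2 of the 35 splits, with a real gap of 24.2 and a highest other of 28.2, so chance cannot be excluded. Noise of dim probes as the only source is argued against by a ratio of 1.55 in the brightest 25% of probes. A single outlying array is argued against as well, since the lowest ratio with 1 high-fat array left out was 1.29. The subtracted 75th percentile of signal varied more among high-fat arrays, with an SD of 15.5 against 4.72 in control arrays. Whether this scaling widened the distances was not tested, nor was an uneven response of mice to the diet.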

How the results depend on the processing

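Normexp, slide column as a block, outlier spots kept and adjustment over accession-named probes alone were chosen after seeing the data. The 262 changed probes (249 higher, 13 lower; long non-coding 134, 125 and 9) became 0 in all 6 counts with no filter, with normexp and with slide column as a block, with 4207, 3159 and 2915 probes at unadjusted p under 0.05 in limma. Chance gives about 1971 on average among 39426 probes, the number tested with normexp and with the block, and another split of the arrays reached 5164. With no filter 60823 probes were tested. They became 98, 93 and 5 (long non-coding 49, 47 and 2) with quantile normalization, 129, 123 and 6 (68, 65 and 3) with the deposited values, and 442, 390 and 52 (228, 203 and 25) at unadjusted p under 0.05 and a fold of at least 2. Lower calls alone moved to 21 with array weights, to 6 (3 long non-coding) with the filter on all 8 arrays and with trend and robust settings, and to 8 (5) at adjusted p under 0.05 and a fitted fold of at least 2, of which 5 (3) have a bound under 2-fold. Leaving out 1 array gave 0 to 616 changed, 0 to 571 higher and 0 to 45 lower probes, and 0 to 331, 0 to 304 and 0 to 27 among long non-coding ones. The count was 0 without control replicates 19, 21 or 25 or high-fat replicates 26, 27 or 39, 345 without control replicate 22 and 616 without high-fat replicate 31. All 262 probes kept their direction wherever tested. None of the 262 overlapped between the diets, so leaving out 1 array could not turn a sign, and this does not speak for the calls. Apart from the loss of probes under the stricter filter, the cause of these changes in count was not tested. Signs near 0 turned for Rab5a (-0.024) and Ppara (-0.077) with quantile normalization and for Acaa2 (0.014) with median centring. With 1 array left out, log2 changes ran from -0.013 to 0.17 for Hyal3, -0.035 to 0.22 for Anxa8, -0.031 to 0.072 for Cep41, -0.092 to 0.080 for Ppara, -0.10 to 0.058 for Acaa2 and -0.17 to 0.036 for Pex11a. Without high-fat replicate 39, Hspb7 was -0.21 and Bambi -0.19, without 31 Lhfp was -0.17 and Lhx1 0.13, and without 27 Rps4l was -0.064. Gm9789 ran from -0.28 to -0.12, Il2 from -0.20 to -0.074, Cpt1a from -0.15 to -0.041, Olfr1307 from 0.026 to 0.17 and Rab5a from 0.015 to 0.17. Cpt1a was -0.15 with quantile normalization. With normexp, Duox1 was 0.32, Spats1 0.051, Lhx1 0.11, Hspb7 -0.10, Gm9789 -0.11 and Il2 -0.063. The diets share no replicate number, so the arrays were paired by slide column alone, in the block given above. The mRNA count, the gene list tests, the planned normexp on mean signals and the planned slide block were not run, and the deposited values hold no named gene. Signal over background limits Spats1 and Hspb7, each well above background on only part of the arrays of 1 diet. Of the 262 calls, 220 were well above background on all 8 arrays. For 8 of the higher calls and 7 of the lower calls, no array of 1 diet was well above background.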

Other observations

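None of the following genes passed the threshold between the diets (limma), and all but Acaa2 were chosen after their values were seen. Apoe, a lipoprotein component, was 8.90 ± 0.02 in control livers and 8.93 ± 0.22 in high-fat livers (SD, n = 4 each). Acaa2 was 7.97 ± 0.04 and 7.94 ± 0.21, and the glycolytic gene Gpi1 was 6.33 ± 0.09 and 6.27 ± 0.12. Prdx2, a peroxide-reducing enzyme, was 5.40 ± 0.14 and 5.36 ± 0.17. The histocompatibility gene H2-Q7, from a family with near-identical copies and so uncertain, was 5.28 ± 0.14 and 5.32 ± 0.25. Actb, the cytoskeletal actin often used as a reference, was 2.13 ± 0.24 and 1.98 ± 0.34, a log2 change of -0.15 with a 95% interval from -0.57 to 0.27. The larger high-fat SD of Apoe and Acaa2 need not be spread between mice. The subtracted 75th percentile had an SD of 15.5 in high-fat and 4.72 in control arrays. With quantile normalization the SE of the Acaa2 change was 0.093, against 0.126 in the planned fit. Of the 43 accession-named probes tested, 39 had an interval within 2-fold either way and 31 within 1.5-fold. Tyr, the pigment enzyme of melanocytes, Mbp, of myelin, and Gabrg1, a neuronal receptor subunit, were not well above background on any of the 8 arrays. They were picked from the 7 of 50 accession-named probes that were not tested. Il2, Lhx1, Olfr1307 and Anxa8 were well above background on all 8 arrays, so the picked genes do not show that the signal is particular to liver.

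The median SD over the 10 spots of a named probe within an array was 0.06, and the median SD between arrays of a diet was 0.20. Of the 43 tested, Spats1 and Il2 had a larger SD between spots than between arrays.

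The mean log2 signal of the 249 higher calls was -0.80 ± 0.33 in control livers and 0.69 ± 0.38 in high-fat livers (SD, n = 4 each). It was highest among control arrays on replicate 22, at -0.35, and lowest among high-fat arrays on replicate 31, at 0.21. Olfr166 followed the same order at these ends, with 2.56 on control replicate 22 and 3.17 on high-fat replicate 31. A single axis held 71.9% of the residual variance of the 262 called probes.

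Probes well above background on all arrays of 1 diet and none of the other numbered 21, with 13 seen under the high-fat diet and 8 in controls. As many or more arose in 14 of the 35 splits. The highest was 299, for control replicate 19 with high-fat replicates 26, 31 and 39 against the other 4 arrays. The first 4 of these had the lowest shares of probes above background, from 64.1% to 68.0%, and the others had 70.3% to 74.2%.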
